A study of Rattus norvegicus with 5 samples.

How the data were processed

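Gene expression was compared between intravascular mononuclear leukocytes of allografted and isografted rat kidneys on 5 dual-colour arrays. Per the labels' protocols, allografts were F344 kidneys placed in LEW recipients, isografts were LEW kidneys placed in LEW recipients, and no immunosuppressive drug was given. The cells were washed out of the graft's blood vessels and passed over a density gradient that depletes granulocytes and red cells. Each array carried cDNA of an allograft sample and of an isograft sample. The allograft was labelled with Cy5 on replicates 1, 3 and 5 and with Cy3 on replicates 2 and 4. The labels call the arrays biological replicates and name no animals, so p-values of single genes rest on the spread between these 5 arrays.

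The authors deposited a table with a log ratio per spot and array, used here as log2 ratios. The scanner, the background correction, the normalization and the log base are not given in the sources used here. The deposited values ran from -5.15 to 5.25, a range that argues against log10 and does not exclude the natural log, so fold sizes hold for base 2. The array medians were 0.02, -0.01, 0.02, -0.01 and 0.03 for replicates 1 to 5, so the ratios had been centred near 0. Their SDs were 0.736, 0.506, 0.521, 0.847 and 0.835. Values were present for 41033, 41697, 42286, 42943 and 43286 of the 44290 spots. Spot intensities and flags were not used here, so signal over background is unknown and the number of arrays limits the precision.

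The direction of the ratios, allograft over isograft, is likely and not stated outright. Its basis is the order of the groups in each sample title and the series' design text. Whether replicates 2 and 4 had already been turned to this direction had to be settled from the values. The plan was to use the correlations between arrays and the gene lists described below: 18 lists shifted when the columns were read as already turned, and 0 when they were not. The correlations between arrays overlapped for shared and opposite dyes and settled nothing by themselves. Spots that change sign with the dye were also looked at after the data were seen. A set of 407 spots had a mean ratio of 2.70, 3.43 and 4.29 on replicates 1, 3 and 5, and of -2.77 and -4.15 on replicates 2 and 4. The spots were picked for following the dye, so these signs were fixed by the choice and do not settle the orientation. Turned columns would give such a change of sign for a spot bright in a single dye. No array was turned again. The 407 spots, each with a mean dye-following ratio above 3, were left out of the tests after the data had been seen.

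The row numbers of the value table were not in register with the probe annotation. Probes of a shared accession number should give similar ratios, but with the row numbers taken as probe numbers their correlation across 2869 pairs was 0.00658. Shifts of up to 500 rows reached at most 0.0710. The layout was taken as 103 rows by 430 columns, 103 being the largest prime factor of the 44290 spots. Spots 430 rows apart in the table had correlations of 0.338, 0.315, 0.0674, 0.453 and 0.391 on replicates 1 to 5, weak on replicate 3. Re-orderings built from all prime factors of the number of spots were then searched, and 7598 distinct orders were tried. A single order gave a correlation of 0.437, against 0.0721 for the second best. In that order the table runs along the rows, listing 215 columns of one parity before those of the other, and the annotation starts at the opposite corner and runs along the columns. Over the 2948 pairs from the remaining accessions the correlation was 0.568. This order was first noticed in a search over all pairs, so the remaining accessions are a cross-check and not an unseen test. Of the 407 dye-following spots, 211 (51.8%) lay on named probes with the row numbers as given, close to the 53.2% of all rows that are named, and 0 did in the recovered order. The gene lists described below, which played no part in the search, gave 0 shifted lists with the row numbers as given (smallest adjusted p = 0.894) and 18 in the recovered order. All gene names below rest on this recovered order.

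The platform annotation gave 1 gene for 23535 probes, several genes for 48 and none for 20707, which may include control features. Symbols were updated through the Entrez number with a RefSeq gene table of the GRCr8 assembly. That table matched 23488 probes, 1 symbol changed, and 47 probes kept the annotation's symbol. Probes of a gene were averaged (5658 of the 14871 genes had more than 1 probe), and probes without a single gene were tested as themselves. Near-identical families, such as the RT1 class I genes and the globins, can share hybridisation, so single members of them are uncertain.

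Ratios were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a graft effect and a dye effect. Rows needed values on at least 4 of the 5 arrays and in both dye orientations, which left 33646 rows, of which 14329 were genes. A two-sided Benjamini-Hochberg adjusted p under 0.05 was called a change. Lists with at least 5 members were tested with camera at its preset correlation of 0.01, over 13314 genes measured on all arrays. With 5 arrays and 2 coefficients, 3 residual degrees of freedom remain. Where camera estimates the correlation, its test rests on those 3 degrees of freedom. At the preset correlation it sets list members against the other genes, so those p-values do not measure the spread between arrays. Gene p-values rest on variances that eBayes moderates across all rows. The fry test was run as well: its PValue tests whether a list's genes move on balance in a direction, and its Mixed value whether they change in either. Neither compares the list with other genes.

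The tests, 27 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Genes named under the rule had a symbol, an adjusted p under 0.05 and the same sign on every array with a value. The 12 largest rises and the 12 largest falls were taken, leaving out symbols that start with LOC or RGD. Each list added up to 3 members with the largest absolute log2 ratio among those that passed over all genes, or, with none passing, the member with the smallest p. The recovered row order, the removal of the dye-following spots, the subtraction of a local trend (a running median over 21 rows by 3 columns of the layout) and a few further gene lists were chosen after seeing the data. The matching of list symbols to synonyms was also tightened after the first results, because it had let related genes stand in for list members; 18 lists were shifted before and after.

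The fit was tested on simulated ratios with the same missing values, the spread of each row after moderation by eBayes and a simulated dye effect. For the comparison of allograft with isograft over 33646 rows, 50 of 50 genes changed 8-fold, 50 of 50 changed 4-fold, 36 of 50 changed 2-fold and 1 of 50 changed 1.5-fold were recovered, with 7 false calls. A list shifted by 0.3 on the log2 scale was called by camera (adjusted p = 1.81e-15). With an estimated correlation the same simulated list had an adjusted p = 0.0575, so at this size that test can miss a true shift. The simulated noise was independent between genes, while the estimated correlation in the real lists reached 0.49, for erythroid markers. The simulation therefore does not show how camera at its preset correlation, or the number of false calls, behaves with correlated genes. The simulated spreads were also more alike between rows than the rows' own fitted spreads, which favours a moderated fit.

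Alternatives were the fit without the dye term, centring, scaling and quantile normalization of the arrays, array weights, a robust variance prior, each probe by itself, stricter and looser filters on missing values, the other reading of the orientation, each array left out, adjustment over named genes alone, an unmoderated fit and a test against a 1.2-fold change. The lists were also tested by camera with an estimated correlation, by camera on ranks and by fry.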

Results

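Transcripts of mononuclear leukocytes collected from the blood vessels of rat renal allografts and isografts were compared on 5 dual-colour arrays, each setting an allograft sample against an isograft sample. F344 kidneys in LEW recipients are rejected acutely but in a self-limiting way, and the series asks what the leukocytes that gather in graft vessels during this rejection express. Ratios are log2, allograft over isograft, ± SE of the limma fit (n = 5 arrays unless stated). Their direction is likely, from the order of the groups in the labels, and gene names rest on a row order recovered from the data. Across genes, the correlation between arrays ran from -0.0147 (replicates 1 and 4) to 0.645 (replicates 1 and 5).

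Among the genes higher in allograft leukocytes were 10 of 44 interferon-response genes, 9 of 29 class I and 6 of 14 class II presentation genes and 7 of 28 cytotoxic genes, and among the lower ones 6 of 10 platelet and 8 of 16 red cell markers. With an estimated correlation none of these lists passed: adjusted p = 0.122 for the interferon list, 0.118 for both presentation lists and the cytotoxic list, and 0.138 for the platelet and red cell lists. Cxcl9, a chemokine induced by interferon gamma, rose most among named genes, 16.9-fold (log2 4.08 ± 0.17, adjusted p = 0.00239). Clec1b, a platelet receptor, and Pf4, the platelet chemokine CXCL4, fell by 3.12 each on the log2 scale (SE 0.22 and 0.19, adjusted p = 0.00431 and 0.00315). In all, 455 of 33646 genes and unnamed probes differed, 256 higher and 199 lower in allograft leukocytes. Of these, 255 were named genes (153 higher, 102 lower) and 200 were probes with no single gene. At least a 2-fold difference was found for 324 of them, 161 higher and 163 lower, of which 195 were named genes. None passed in an unmoderated limma fit (4501 at an unadjusted p under 0.05), 197 passed against a 1.2-fold change, 749 with quantile normalization and 2086 after subtraction of a local trend, an alternative chosen after seeing the data. With arrays scaled to a common spread, 317 passed, 99 higher and 218 lower, and the higher share moved from 56.3% to 31.2%. The counts rested on all arrays: 77, 157, 111, 69 and 65 passed without replicate 1, 2, 3, 4 or 5. Of the 255 named genes, 8 were olfactory or vomeronasal receptor genes, a set chosen after seeing the data. They were 0.768% of the 1042 such genes tested, against 1.86% of other named genes. These receptors have no known role in leukocytes, so the calls may hold more false ones than the threshold implies. The naming rule took 65 genes, of which 58 passed. Of these 58, 21 passed with any array left out, and 17 passed in none of those 5 fits: Bak1, Cdkn3, Nuf2, Stmn1, Icam1, Cd40, Pfkp, Slc2a1, Il18, Apoe, Ctsz, Ctsc, RT1-Db2, Fcgr2b, Entpd1, Icos and Cd3e. Other genes named below are not part of this tally. With arrays scaled to a common spread 26 of the 58 lost their call, their log2 ratios being no smaller and of the same sign: Vcam1 (adjusted p = 0.0697), C2 (0.0508), Cfb (0.0552), Ifng (0.0931), Psmb9 (0.0519), Tap1 (0.0553), Psme2 (0.0601), RT1-Da (0.0563), RT1-Ba (0.0501), RT1-Db2 (0.0779), C1qa, Cd14, Cst7, Cdkn3, Nuf2, Stmn1, Cd40, Pfkp, Slc2a1, Il18, Apoe, Ctsz, Ctsc, Fcgr2b, Entpd1 and Cd3e. In other settings Entpd1 lost its call with quantile normalization (adjusted p = 0.0569), array weights (0.0602), a robust variance prior (0.0501) and the dye-following spots kept (0.0508). Ctsc lost it without the dye term (0.0512) and with array weights (0.0531), Il18 with array weights (0.0531), and Apoe with probes measured on all arrays (log2 0.25, adjusted p = 0.610).

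The other 11 of the 12 largest rises were of several kinds, among them chemokines, complement genes, metabolic enzymes and surface proteins. Hk3, a hexokinase of myeloid cells, rose by 3.25 ± 0.17, Cxcl11 by 3.11 ± 0.16, the fatty acid binding protein Fabp5 by 3.10 ± 0.17 and the adhesion molecule Vcam1 by 3.02 ± 0.28. Ubd, a ubiquitin-like protein induced by interferon gamma and tumour necrosis factor, rose by 2.86 ± 0.16. Acod1, which makes itaconate in activated macrophages, rose by 2.77 ± 0.13. The complement genes C2 and Cfb rose 6.74-fold and 5.64-fold (SE 0.19 and 0.20 on the log2 scale). Xcl1, a chemokine of activated cytotoxic lymphocytes, rose by 2.67 ± 0.20, Lag3, an inhibitory receptor of activated T cells, by 2.48 ± 0.18, and the membrane metalloproteinase Mmp14 by 2.47 ± 0.14. Each was above 0 on 5 of 5 arrays, and the adjusted p-values ran from 0.00241 to 0.00756. Vcam1 lost its call in at least 1 of the fits that left out an array.

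**Figure D1:**
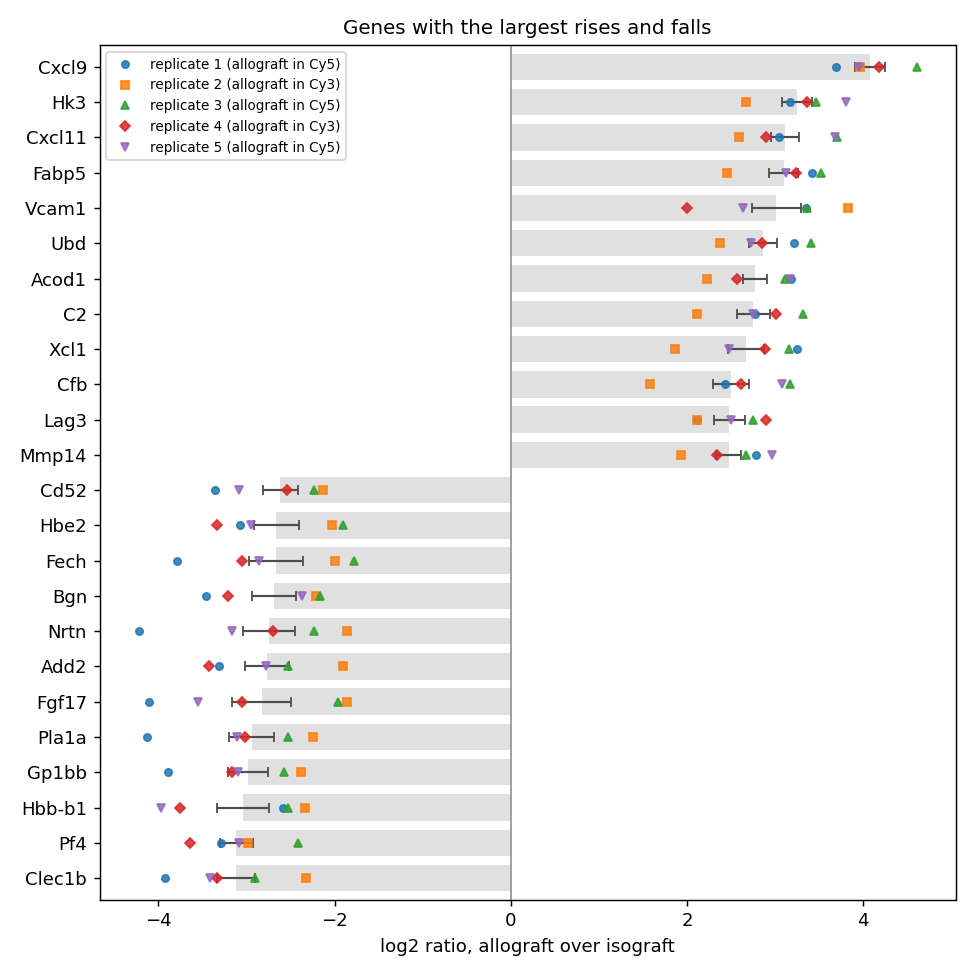
The 12 named genes with the largest rises and the 12 with the largest falls. The horizontal axis is the log2 ratio of allograft over isograft; bars are the fitted value, whiskers ± 1 SE, and points the 5 arrays, with the dye of the allograft in the key. All 5 points lie on the same side of 0 for each gene, from 3.70 to 4.61 for Cxcl9 and from -3.92 to -2.32 for Clec1b.

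Interferon-response genes were higher as a list: 10 of 44 tested members rose and 1 fell (24 and 3 adjusted over the list alone), with a mean log2 ratio of 0.71 (SD 0.98 across members, camera adjusted p = 8.60e-15). The adjusted p = 0.122 with an estimated correlation. Besides Cxcl9 and Cxcl11, Cxcl10 rose by 2.44 ± 0.21, although its 2 probes differed, at 0.31 and 4.57. The guanylate-binding proteins Gbp2, Gbp4 and Gbp5 rose by 2.01, 1.92 and 1.91, the immunity-related GTPases Irgm and Ifi47 by 1.81 and 1.70, and the transcription factor Irf1 by 1.57. Parp9 rose by 0.90, and Rsad2 fell by 1.14 (SE 0.15, adjusted p = 0.0234). Members that did not pass included Bst2 (1.37, adjusted p = 0.0505), Isg15 (1.00, adjusted p = 0.0559), Ifit2 (0.83), Stat2 (0.69), Usp18 (0.60), Mx1 (0.24), Ifit1 (0.26), Irf7 (0.03) and Oas1a (-0.46).

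Of 32 chemokines, 7 rose and 1, Pf4, fell (9 and 1 adjusted over the list alone; mean 0.46, SD 1.28, camera adjusted p = 3.26e-04, and adjusted p = 0.122 with an estimated correlation). Ccl6, Ccl4 and Ccl3 rose by 1.77, 1.44 and 1.01, beside the 3 CXCR3 ligands and Xcl1. Ccl5 (-0.20) and Cxcl12 (-0.05) did not pass. Inflammatory cytokines and mediators were shifted upwards as a list, with 3 of 33 rising (9 rising and 3 falling adjusted over the list alone; camera adjusted p = 0.00759, and adjusted p = 0.138 with an estimated correlation). These were Ifng, interferon gamma itself (1.76 ± 0.16, adjusted p = 0.00756), the inflammatory caspase Casp4 (1.40 ± 0.15) and Il18 (0.91 ± 0.15, with probes at 0.33 and 1.45). Il1b (0.92, adjusted p = 0.0513), Tnf (0.52), Nos2 (0.60), Il6 (0.15) and Il10 (-0.12) did not pass.

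Of 29 class I processing and presentation genes, 9 rose and none fell (25 and 0 adjusted over the list alone), 28 were above 0, and the mean was 0.75 (SD 0.36, camera adjusted p = 2.03e-22, and adjusted p = 0.118 with an estimated correlation). The immunoproteasome subunit Psmb9 rose by 1.61 ± 0.14, the peptide transporter Tap1 by 1.51 ± 0.16 and the proteasome activator Psme2 by 1.18 ± 0.14. Of 14 class II genes, 6 rose and none fell (8 rising and 1 falling adjusted over the list alone; mean 0.60, camera adjusted p = 5.69e-09, and adjusted p = 0.118 with an estimated correlation). RT1-Da and RT1-Ba rose by 1.31 ± 0.13 and 1.26 ± 0.13, RT1-Db2 rose 2.30-fold (SE 0.14 on the log2 scale), and Ciita, the class II transactivator, rose by 0.94. The donor strains differ at class I genes, while recipients were LEW in both groups. RT1 genes resemble each other, so probes of this family can cross-hybridise.

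Among 24 complement genes 3 rose, C2, Cfb and C1qa (9 rising and 1 falling adjusted over the list alone; mean 0.53, camera adjusted p = 0.00154, and adjusted p = 0.122 with an estimated correlation). C1qa rose by 1.86 ± 0.17, its 2 probes standing at 1.17 and 2.55. C3 (0.37) and C5 (-0.30) did not pass.

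In the NK cell and cytotoxic list 7 of 28 rose (7 rising and 2 falling adjusted over the list alone; mean 0.43, camera adjusted p = 6.54e-06, and adjusted p = 0.118 with an estimated correlation). With Xcl1 and Ifng they included Cst7, an inhibitor of lysosomal cysteine proteases in cytotoxic cells (1.46 ± 0.16), the granzyme gene Gzmc (1.29), Klrk1, which encodes NKG2D (1.16), Faslg (0.92) and Nkg7 (0.84). Gzmb (0.43), Prf1 (0.30) and the NK receptor Ncr1 (-0.61) did not pass. Of 24 T cell markers, Icos (1.16 ± 0.13) and Cd3e (1.10 ± 0.15) rose (5 rising and 2 falling adjusted over the list alone), and the list's mean was 0.08 (camera adjusted p = 0.364). Cd4 (0.06), Cd8a (0.16), Ccr7 (-0.74) and Lef1 (-0.81) did not pass. In the co-inhibition list Lag3 and Entpd1 (0.79 ± 0.13) rose, 2 of 16 (2 adjusted over the list alone), while Pdcd1 (0.24) and Ctla4 (-0.17) did not pass. That list's mean was 0.09, its median -0.08 and its camera adjusted p = 0.616.

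Myeloid markers were mixed. Of 34 monocyte and macrophage markers 3 rose, the endotoxin co-receptor Cd14 (1.42 ± 0.17), Apoe (1.04 ± 0.14, with probes at 0.25 and 2.22) and Aif1 (1.02). The inhibitory Fc receptor Fcgr2b fell by 1.28 (SE 0.14). The list's mean was 0.11, with 7 rising and 3 falling adjusted over the list alone (camera adjusted p = 0.0247, and adjusted p = 0.138 with an estimated correlation), and it no longer passed without replicate 1 (adjusted p = 0.0914) or 2 (0.113), with each probe by itself (0.0573) or with probes measured on all arrays (0.0573). Csf1r (-0.09), Ccr2 (-0.85) and Cd163 (0.09) did not pass. The lysosomal proteases Ctsz (1.00 ± 0.14) and Ctsc (0.93 ± 0.15) rose among 28 lysosome and phagocytosis genes (11 rising and 1 falling adjusted over the list alone; mean 0.26, camera adjusted p = 1.03e-04, and adjusted p = 0.122 with an estimated correlation). Of 16 dendritic cell markers the co-stimulatory receptor Cd40 rose (1.21 ± 0.14; 2 adjusted over the list alone), with a list mean of 0.09 (camera adjusted p = 0.608).

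Of 54 cell cycle genes 8 rose (27 rising and 1 falling adjusted over the list alone), 47 were above 0 and the mean was 0.46 (SD 0.41, camera adjusted p = 5.13e-13, and adjusted p = 0.138 with an estimated correlation). Cdkn3 rose by 1.33 ± 0.19, the kinetochore gene Nuf2 by 1.18 ± 0.17, Stmn1 by 1.13 ± 0.17 and cyclin A2 (Ccna2) by 1.03. Mki67 (0.71, adjusted p = 0.0832) and Top2a (-0.06) did not pass. Of 24 glycolysis genes 4 rose, Hk3, Pfkp (1.22 ± 0.15), the glucose transporter Slc2a1 (1.11 ± 0.13) and Tpi1 (1.08), with 9 adjusted over the list alone (mean 0.47, camera adjusted p = 1.92e-06, and adjusted p = 0.138 with an estimated correlation). Oxidative phosphorylation genes were shifted together and by little: none of 45 passed (5 rising adjusted over the list alone), and the mean was 0.28 (SD 0.23, camera adjusted p = 2.88e-09, and adjusted p = 0.122 with an estimated correlation). Cytochrome c (Cycs) stood at 0.81 ± 0.14 (adjusted p = 0.0528). Its 4 probes ran from 0.009 to 1.05, with 3 passing when fitted singly, and the gene passed without the dye term (adjusted p = 0.0353). Of 29 apoptosis genes 5 rose (11 adjusted over the list alone; mean 0.35, camera adjusted p = 3.31e-06, and adjusted p = 0.159 with an estimated correlation). They were Casp4, Birc3 (1.23 ± 0.14), Bak1 (0.95 ± 0.14), Cflar (0.91) and Fas (0.79), which include both promoters and inhibitors of cell death.

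**Figure D2:**
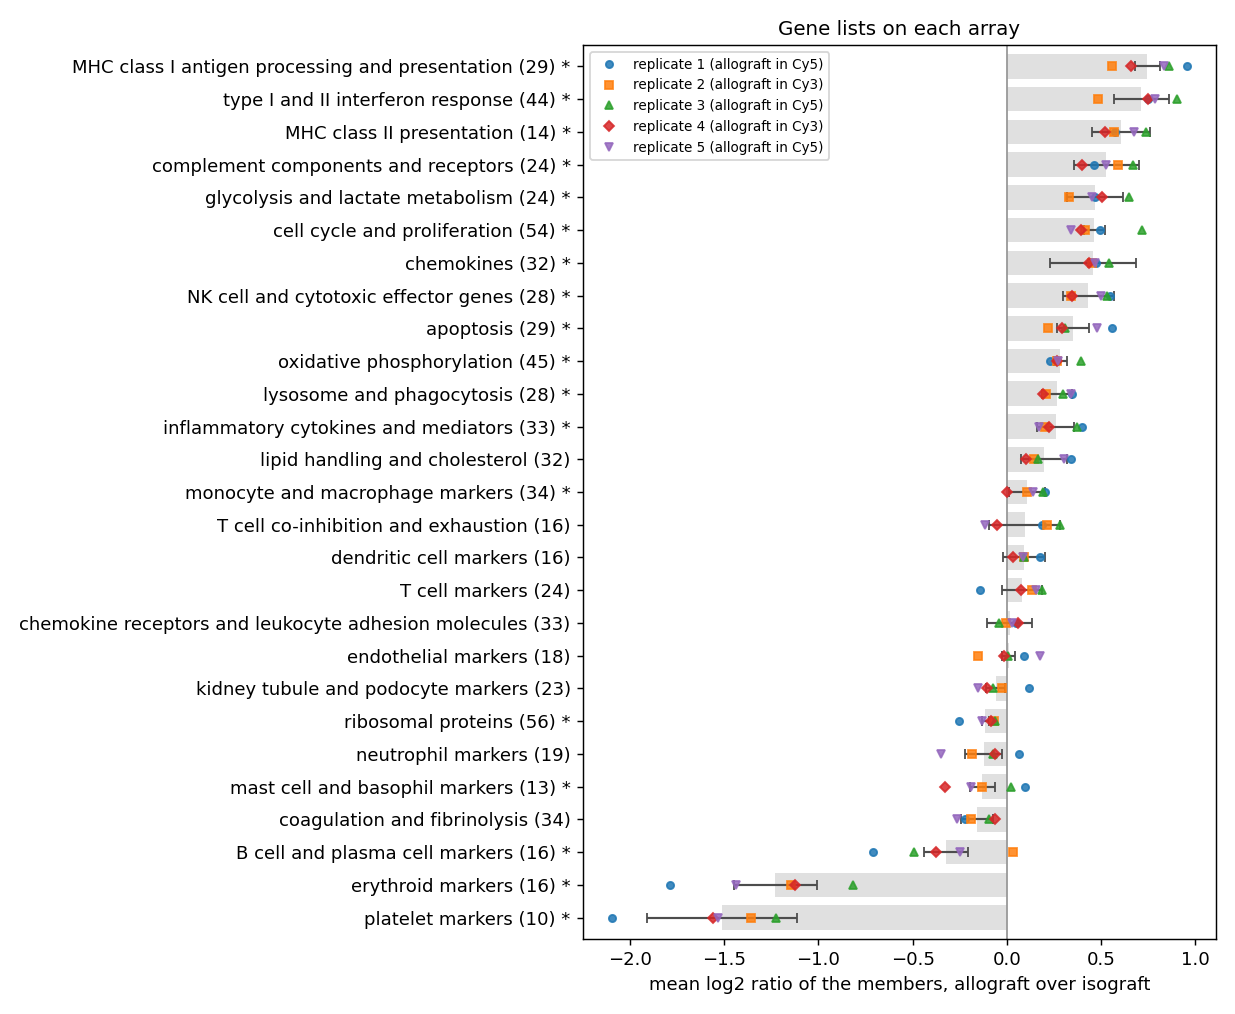
Mean log2 ratio of each gene list, allograft over isograft. Bars are the mean of the fitted member values, whiskers ± 1 SE across members, points the mean of the members on each of the 5 arrays, numbers in brackets the members tested, and asterisks a camera adjusted p under 0.05 at the preset correlation. The list means run from 0.75 for class I presentation to -1.51 for platelet markers, whose 5 arrays lie between -2.10 and -1.23.

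Of 10 platelet markers 6 fell (6 adjusted over the list alone), all 10 were below 0 and the mean was -1.51 (SD 1.26, camera adjusted p = 4.14e-10, and adjusted p = 0.138 with an estimated correlation). With Clec1b and Pf4, the von Willebrand receptor subunit Gp1bb (-2.98 ± 0.23), Treml1 (-2.23), Gp5 (-1.32) and Vwf (-1.31) fell, whereas Ppbp (-0.38) and Itgb3 (-0.20, 4 arrays) did not pass. Of 16 erythroid markers 8 fell (12 adjusted over the list alone), all 16 were below 0 and the mean was -1.23 (SD 0.88, camera adjusted p = 5.13e-13, and adjusted p = 0.138 with an estimated correlation). Beta-globin Hbb-b1 (-3.04 ± 0.29), Hbb (-2.27 ± 0.24, its 2 probes at -3.73 and -0.80) and the globin chaperone Ahsp (-1.98 ± 0.25) fell. The gradient had been used to deplete red cells, per the labels.

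Of the 12 largest falls, 4 were members of these lists: Clec1b, Pf4, Gp1bb and Hbb-b1. The others included Add2, a red cell membrane skeleton protein (-2.77 ± 0.25), Fech, the last enzyme of haem synthesis (-2.66 ± 0.31), and the globin Hbe2 (-2.66 ± 0.26). The rest were the phospholipase Pla1a (-2.94 ± 0.25), the growth factors Fgf17 (-2.83 ± 0.33) and Nrtn (-2.74 ± 0.29), the proteoglycan Bgn (-2.69 ± 0.24) and the lymphocyte surface glycoprotein Cd52 (-2.61 ± 0.20). Adjusted p-values of the 12 ran from 0.00315 to 0.0165, with each gene below 0 on 5 of 5 arrays. Fgf17, Nrtn, Fech and Hbe2 lost their call in at least 1 of the fits that left out an array.

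Of 34 coagulation and fibrinolysis genes 4 fell, F2rl2 (-1.47 ± 0.16), Vwf (-1.31 ± 0.17, with probes at -1.88 and -0.74), F13a1 (-1.26 ± 0.16) and Procr (-0.84), with 5 falling and 1 rising adjusted over the list alone. The list was not shifted (mean -0.16, median 0.00, camera adjusted p = 0.0850), except without replicate 4 (adjusted p = 0.0075) and after subtraction of a local trend over the array (adjusted p = 0.0325).

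B cell and plasma cell markers were lower as a list (mean -0.32, SD 0.47, camera adjusted p = 0.00313, and adjusted p = 0.328 with an estimated correlation). None of the 16 passed over all genes, with 5 falling and 1 rising adjusted over the list alone. Fcrla (-0.85 ± 0.15, adjusted p = 0.0514), Cd79b (-1.11, adjusted p = 0.0559) and Ms4a1, which encodes CD20 (-0.85), were among the lowest, and Prdm1, a regulator of plasma cells, stood at 0.67. On replicate 2 the list's mean was 0.03, against -0.71 on replicate 1. Ribosomal protein genes were shifted down slightly (mean -0.11, SD 0.14, none of 56 passing over all genes or over the list alone, camera adjusted p = 0.00220, and adjusted p = 0.364 with an estimated correlation), with Rps29 at -0.47 ± 0.14. Mast cell and basophil markers were lower by a mean of 0.13 on the log2 scale as a list (camera adjusted p = 0.0172, and adjusted p = 0.270 with an estimated correlation). None of the 13 passed (1 falling adjusted over the list alone; Tpsb2 -0.61 ± 0.14), and the list no longer passed without replicate 4 (adjusted p = 0.112) or 5 (0.102). For scale, 1042 olfactory and vomeronasal receptor genes, a set chosen after seeing the data, had a mean of -0.13 (SD 0.27), so the ribosomal and mast cell means were no lower than that of genes with no known role in leukocytes.

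The lists of markers of other cells that the preparation could hold were not shifted. Endothelial markers had a mean of 0.01 (SD 0.15, median -0.01, 18 members, camera adjusted p = 0.946), with Kdr at -0.36 ± 0.13 (adjusted p = 0.297). That list did not hold Vcam1 (3.02), Icam1 (1.14), Vwf (-1.31) or Procr (-0.84), which were called and stand in other lists. Kidney tubule and podocyte markers had a mean of -0.06 (SD 0.24, 23 members, camera adjusted p = 0.491), with Spp1 at 0.63 ± 0.22 (adjusted p = 0.256). Neutrophil markers had a mean of -0.12 (SD 0.42, 19 members, camera adjusted p = 0.172), with Alpl at 0.78 ± 0.22 (adjusted p = 0.172). No member of these 3 lists passed over all genes or over the list alone. Neutrophil markers did pass without replicate 4 (adjusted p = 0.0426) and after subtraction of a local trend (0.0325).

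Chemokine receptors and adhesion molecules were not shifted as a list (mean 0.01, median -0.15, camera downward with adjusted p = 0.413), but Vcam1 and Icam1 (1.14 ± 0.15) rose, 2 of 33 (4 rising and 5 falling adjusted over the list alone). Cxcr3 (0.42), Cx3cr1 (-0.33) and Cxcr4 (-0.82, adjusted p = 0.0800) did not pass. Lipid handling genes had a mean of 0.20 (camera adjusted p = 0.0850), with Fabp5 and Apoe rising, 2 of 32 (5 rising and 2 falling adjusted over the list alone). This list passed without replicate 4 (adjusted p = 0.0360) and after subtraction of a local trend (0.0473).

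In all, camera called 18 of 27 lists, 13 higher and 5 lower. With an estimated correlation it called 0, with 9 at an unadjusted p under 0.05, and fry called 17. Lists share members, so the called lists are not independent. Cxcl9, Cxcl10 and Cxcl11 are in the interferon and chemokine lists, and Xcl1 is in the chemokine and cytotoxic lists. Ifng is in the cytokine and cytotoxic lists, and Casp4 in the cytokine and apoptosis lists. The fry test did not call the B cell (adjusted p = 0.0967), mast cell (0.0696) and ribosomal protein (0.0700) lists, 3 of the 5 lower ones, and it called the dendritic cell (0.0111) and lipid handling (0.0188) lists, which camera did not. No gene or probe passed for a dye effect in the limma fit, and an unmoderated fit gave 0 as well. An unadjusted p under 0.05 was found for 3823 of 33646 for the dye effect and for 4486 for the graft effect (1682 expected by chance). For the graft effect, 14.4% of the olfactory and vomeronasal receptor genes reached that level, against 15.2% of other named genes. The excess over chance is thus weak evidence of graft effects by itself. Across genes the SD of the dye effect was 0.28 on the log2 scale, against 0.35 for the graft effect. These counts leave out the 407 dye-following spots. With them, 465 passed for a dye effect.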

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

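The tests of RT1 genes and of a general rise of leukocyte genes were chosen only after their results had been seen. The further platelet and erythroid lists were chosen after the main results had been seen, with their bounds written before these lists were computed. Of 92 series of 5 array values (named genes and list means), 3 had an array far from the rest, and chance gives about 5%, so these 3 are no more than chance gives. For Birc3, replicate 2 stood at 0.75 against 1.32 to 1.47 on the other arrays (gap over range 0.793). For Cxcl10, replicate 2 stood at 1.39 against 2.62 to 3.01 (0.758). For the mean of oxidative phosphorylation genes, replicate 3 stood at 0.39 against 0.23 to 0.27 (0.726).

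The fall of platelet and erythroid genes may reflect less RNA of those cells in the allograft preparations. If so, platelet and erythroid genes outside the fixed lists should be lower too, with both medians below -0.3. The erythroid median was -0.53 (17 of 20 genes below 0), but the platelet median was -0.247 (14 of 20 genes below 0), short of that bound and not at 0 either, so this stays open. Abundant platelet transcripts were uneven, Pf4 at -3.12 and Ppbp at -0.38, Plek, which leukocytes also express, rose by 0.99, and the platelet list shares Pf4 and Ppbp with the chemokine list and Vwf with the coagulation list. A local trend over the array does not account for the fall, since the mean of the 26 markers was -1.34 (SE 0.20 across markers) before and -1.322 (SE 0.20) after its subtraction. Carry-over of blood, the density gradient, and true differences in circulating cells between recipients were not tested against each other.

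The rise of class I presentation genes could come from strain variants at RT1 genes, since the donor strains F344 and LEW differ there. Recipients were LEW in both groups, so such a variant could act only through F344 donor cells in the allograft samples. The share of donor cells is not known. The 14 members outside the RT1 genes had a mean log2 ratio of 0.699 (SE 0.13 across genes), against 0.79 (SE 0.05) for the 15 RT1 members. This argues against strain variants as the whole cause. The SEs in this paragraph are across genes, treat related genes as independent and do not measure the spread between arrays. A smaller share of platelet and red cell RNA would lift leukocyte genes alike. Class I members lay above T cell markers by 0.665 (SE 0.13 across genes), which an even lift alone would not give. The share of T cells among the leukocytes is not known and may itself differ, so this comparison does not decide. A higher share of cells rich in class I transcripts, and induction within cells, stay open and were not tested.

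For the 455 genes and probes that differed, the signs of the 5 arrays were also set in the 14 other ways that can be fitted beside the dye, 15 with the real one. The real signs were the only 1 of 15 with as many calls, and the highest other count was 0. With 15 patterns the share cannot be under 0.05.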

How the results depend on the processing

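The subtraction of a local trend, the row numbers as given, the dye-following spots kept and the unmoderated test of the dye were chosen after seeing the data. The 455 calls became 749 with quantile normalization, 197 against a 1.2-fold change, 2086 after the local trend was subtracted (the 455 all among them) and 0 in an unmoderated limma fit (4501 at an unadjusted p under 0.05). Between 65 and 157 passed without an array, all at least 2-fold, against 324 of that size with all arrays. With arrays scaled to a common spread 99 rose and 218 fell. Under the other reading of the orientation, counts were 0 for genes (3823 at an unadjusted p under 0.05), 0 at 2-fold and 0 for lists, while 455 followed the dye. That reading only swaps the graft and dye effects of the same fit. Its gene counts and ratios therefore restate the dye effects of the main fit and are no separate outcome. Dye effects numbered 14 with arrays scaled, 365 after the local trend was subtracted and 465 with the dye-following spots kept. Shifted lists numbered 0 with an estimated correlation and 0 with the row numbers as given, and 17 to 20 without an array. Except for the local trend, whose test stands with the observations, the cause was not tested.

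Of 58 named genes that passed, 21 passed with any array left out and 17 with none of the 5 fits. None changed sign except under the other reading of the orientation, where Lag3 (-0.027), Pf4 (0.189), Hbb-b1 (0.012), Bgn (0.025), Hbe2 (0.017), F2rl2 (0.024), Vwf (0.094), F13a1 (0.347), C1qa (-0.033), Slc2a1 (-0.0019), Ctsc (-0.260) and Fcgr2b (0.123) did. Of the named genes that had not passed, Kdr (0.079), Spp1 (-0.407) and Tpsb2 (0.021) changed sign there. There too, the sign changed for the means of chemokine receptors (-0.005), kidney (0.023), mast cell (0.117), neutrophil (0.0022) and T cell markers (-0.023). List means near 0 changed sign elsewhere. Chemokine receptors stood at -0.0024 with arrays scaled, -0.021 with quantile normalization, -0.017 with each probe by itself and -0.00031 with probes on at least 3 arrays. Endothelial markers stood at -0.018 with arrays scaled, -0.017 with quantile normalization, -0.0024 with probes on all arrays, -0.033 with the local trend subtracted, and from -0.026 (without replicate 4) to 0.044 (without replicate 2) when an array was left out. With arrays scaled, 26 named genes lost their call. Signal over background is unknown, so its limit on dim genes cannot be stated.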

Other observations

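The gene lists of this part and the genes picked from the table of all genes were chosen after their values or the main results were seen, and the bound for the test of the local trend was set before. Camera p-values of these further lists were adjusted over the further lists alone. They therefore cannot be set against the adjusted p-values of the 27 fixed lists, which form a larger family. Standard proteasome subunits were higher as a list: 29 of 30 were above 0, with a mean log2 ratio of 0.29 (SE 0.04 across members, camera adjusted p = 7.28e-08, and adjusted p = 0.038 with an estimated correlation). Psmb2 rose by 0.85 over all genes tested, and 5 rose adjusted over the list alone. Endoplasmic reticulum chaperones had a mean of 0.15 (16 genes, camera adjusted p = 0.00546, and adjusted p = 0.15 with an estimated correlation), with none passing over all genes, 2 rising adjusted over the list alone and Hspa5 at 0.61. Of 22 glutathione and thioredoxin genes, Txn1, the cytosolic thioredoxin, rose by 2.10 (adjusted p = 0.00590), while Gpx1 (-0.78) and Cat (-0.62) did not pass. Adjusted over the list alone 5 rose and 2 fell, 7 of 22 were below 0, and the list's mean was 0.16 (camera adjusted p = 0.0453, and adjusted p = 0.144 with an estimated correlation). The platelet and erythroid genes outside the fixed lists had means of -0.28 (camera adjusted p = 0.00532, and adjusted p = 0.133 with an estimated correlation) and -0.46 (camera adjusted p = 7.24e-06, and adjusted p = 0.133 with an estimated correlation). Adjusted over the list alone, 6 of 20 platelet genes fell and 1 rose, and 10 of 20 erythroid genes fell. Only 4 Gimap genes were measured, with a mean of 0.03, and were not tested as a list.

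Several called genes stood outside both the lists and the naming rule. Gpr84, a receptor for medium-chain fatty acids on activated myeloid cells, rose by 2.26 (4 arrays), Lacc1 by 2.11, the kinase Sgk1 by 2.09, the glucose transporter Slc2a6 by 1.98 and the fatty acid transporter Slc27a2 by 2.36. Il18bp, the secreted inhibitor of interleukin 18, rose by 1.46, beside Il18 itself. Selenbp1 (-2.45), Clu (-2.13) and Gfi1b, a transcription factor of the platelet and red cell lineages (-1.90), fell.

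Olfactory and vomeronasal receptor genes, which have no known role in leukocytes, were looked at as a set. Of 1042 tested, 8 passed (0.768%), against 247 of 13287 other named genes (1.86%). An unadjusted p under 0.05 was found for 150 of the 1042 (14.4%) and for 2025 of the others (15.2%), where chance alone gives 5%. An unadjusted p under 0.05 is thus weak evidence for a single gene here. The shares of receptor genes and other genes were not tested against each other. If none of the receptor genes truly differed, the 8 that passed would be false calls. The adjusted calls may then hold more false ones than the threshold of 0.05 implies. The mean log2 ratio of the receptor genes was -0.13 (SD 0.27).

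The larger count of calls after subtraction of a local trend may come from noise bound to the position of spots. Probes of a shared accession lie apart on the array, so such noise should weaken their agreement. Their correlation was higher after the subtraction on 5 of 5 arrays, going from 0.325, 0.322, 0.609, 0.179 and 0.241 to 0.409, 0.398, 0.630, 0.267 and 0.305 for replicates 1 to 5. The subtraction was not made the main setting, since it was chosen after seeing the data.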
